A study of Mus musculus with 8 samples.

How the data were processed

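RNA from E11.5 mouse embryos was measured on 8 Affymetrix arrays, 4 from controls and 4 from FAK mutants. Per the labels, 1 control and 1 mutant array came from p75-sorted cranial neural crest cells, each a pool of 3 embryos, and the other 6 arrays came from origins named LM, OFT and UM, again 1 control and 1 mutant array each. The labels do not spell out LM, OFT and UM, so these names are kept as they stand. The embryonic day of these 6 arrays is that of the series title. The number of embryos behind each LM, OFT or UM array is not given in the sources used here. Each origin had 1 array per genotype. The error term is therefore how much the mutant-minus-control difference varied between origins. The p-values rest on that spread and not on replicate samples of an origin.

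The deposited values are intensities on a linear scale, 1 per probe set, for 45101 probe sets. The software that made them is not given in the sources used here. Their scaling shows in the values: the mean intensity between the 2nd and 98th percentiles was 149.951 to 149.957 on all 8 arrays. No further scaling was applied, because the median log2 values of the arrays, 5.95 to 6.08, lay within the range of 0.2 set in advance. Intensities were turned into log2(intensity + 32). An intensity of 0 is then a log2 value of 5, and fold changes of dim genes are understated. The number of arrays limits the precision.

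Probe sets were named through the platform annotation supplied with the series. It gave exactly 1 gene for 34945 probe sets and several genes for 932, which were left out; 9211 probe sets were not listed and stayed unnamed. The 64 Affymetrix control probe sets were kept for array quality only. Updating symbols through Entrez identifiers and the GRCm38.p6 gene table changed 0 symbols. Each of 18193 genes was represented by its brightest probe set. A gene was tested if at least 2 of the 8 arrays lay above the 40th percentile of all values, an intensity of 19.4, which left 13543 genes. No genome build goes with the array values, so no coordinates are given.

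The model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a term for each origin and 1 for genotype, 3 residual degrees of freedom and a prior of 9.18. Pairing of control and mutant arrays came from the origin label. As a check, deviations of arrays from their genotype means were correlated between the control and mutant array of each origin. The correlation was 0.877 for p75-sorted cells, 0.616 for LM, 0.789 for OFT and 0.665 for UM. A shared tissue type alone would give positive values, so the check is a weak one. The log2 values of the LM mutant correlated at 0.981 with the LM control and at 0.983 with the UM control. The 4 contrasts tested were mutant against control, OFT against the mean of LM and UM, LM against UM, and p75-sorted cells against the mean of LM, OFT and UM. In the contrasts of origins the control and mutant arrays of an origin served as its replicates. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Values after ± are limma's moderated SE, in which the spread of a gene is drawn toward that of all genes.

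A set of 23 gene lists, holding 397 distinct genes of which 24 had no probe set, was fixed before the data were examined. They covered focal adhesion, extracellular matrix, neural crest, lower and upper jaw patterning, cardiac muscle, outflow tract and second heart field, smooth muscle, endothelium, erythroid cells, macrophages and leukocytes, epithelium, neurons, glia, skeletal muscle, cell cycle, p53 targets and apoptosis, axon guidance, cartilage and bone, hypoxia and glycolysis, immediate early and heat shock genes, and sex-linked genes. The last list was reported as values only. A further list was tested and counted with the others but is not described here. In all, 22 lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and limma's fry were the alternatives.

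Genes named in the text followed a rule fixed in advance. For each contrast it took the 10 higher and 10 lower genes with the largest fold among those past the threshold, filled up where fewer passed by the smallest unadjusted p among genes with the same sign in every pair. It also took up to 4 members of each list with the largest change. In each origin it took the 5 largest increases and 5 largest decreases among genes whose higher value lay above the median of tested values. Within an origin there is 1 array per genotype, so differences carry no test, and list medians were placed among 10000 random lists of the same size matched on mean signal.

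On simulated data of 13543 genes with 200 changed, 2-fold changes were recovered for 100% of genes in the genotype contrast, 88% for OFT, 53% for LM against UM and 92% for p75-sorted cells. Of the calls, 3.8%, 6.9%, 5.6% and 7.2% were false in the same order. The simulated errors were independent between genes, and the simulated genotype change was the same in every origin. Measured differences were not like this, since across genes those of LM and UM correlated at -0.33. The 100% therefore does not cover genotype changes that differ between origins. Alternatives were quantile normalization, pseudocounts of 1 and 100, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, an intensity trend with a robust prior, array weights, the genotype fit without the origin term, and leaving out each array or pair. A fit on the 6 LM, OFT and UM arrays was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

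Ptk2, which encodes FAK, has 0 probe sets in the annotation used here, so the transcript of the mutated gene was not analysed here and the genotype labels were not checked against it. Its relative Ptk2b has 2 probe sets, and it did not pass the signal filter.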

Results

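Transcript levels were compared between FAK mutant and control E11.5 mouse embryos, in cranial neural crest cells sorted for p75 and in 3 further origins labelled LM, OFT and UM. FAK, focal adhesion kinase, is a tyrosine kinase of integrin adhesion sites. Each origin had 1 control and 1 mutant array. p75, the product of Ngfr, is a surface receptor carried by neural crest cells and used to sort them.

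The arrays of p75-sorted cells stood apart in some of their control probe sets. The ratio of the 3' to the 5' control probe set of Gapdh was 2.82 in the p75-sorted control and 4.91 in the p75-sorted mutant, against 0.700 to 0.986 on the other 6 arrays. The same ratio for Actb did not stand apart. It was 1.57 in the p75-sorted control and 1.65 in the p75-sorted mutant, against 1.42 to 1.94 on the other 6 arrays. The signal of the 18S control probe set was 6083 and 8542 on the p75-sorted arrays and 314 to 1228 elsewhere. Only this pair is described as sorted and pooled in the labels, so a batch and the origin cannot be told apart for it, and whether RNA degradation or another amplification lies behind these values was not tested. Among the other 6 arrays the spike-in controls were brightest on the LM control, with a geometric mean intensity of 2531 against 885 to 1206.

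Mutant against control asks which transcripts change in cells of FAK mutant embryos across the 4 origins. The neuron list lay lower in the mutants, with 16 of 17 members below 0 and a median log2 difference of -0.30; its camera adjusted p was 3.5e-10, and adjusted p = 0.54 with an estimated correlation. Nefl and Prph, which encode neuronal intermediate filament proteins, differed by -0.67 ± 0.30 and -0.60 ± 0.17 (moderated SE, n = 4 pairs), and Stmn3, a regulator of microtubules, by -0.61 ± 0.19. In the LM pair Nefl, Prph and Stmn3 differed by 0.904, 0.006 and 0.204, and they were lower in every other pair. The skeletal muscle list lay higher, with 13 of 14 members above 0, a median of 0.25 and a camera adjusted p of 3.5e-10, and adjusted p = 0.28 with an estimated correlation. Myod1 and Myf5, which specify muscle precursors, differed by 0.55 ± 0.12 and 0.47 ± 0.13. The cardiac muscle list had a median of 0.15, a camera adjusted p of 3.7e-05, and adjusted p = 0.40 with an estimated correlation. It was led by Actc1, the cardiac alpha actin, at 0.55 ± 0.13. Actc1 differed least in OFT, by 0.205, against 0.584 to 0.773 in the other pairs. The list median, in contrast, was highest in OFT, at 0.26.

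None of the 3 calls held with an estimated correlation. No member of these lists passed the test over all genes. Adjusted over the list alone, 4 skeletal muscle genes and 1 cardiac muscle gene passed, and 0 neuron genes. Fry called 0 of the 22 lists.

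Across all 13543 genes, limma called 0 genes between mutant and control. At an unadjusted p under 0.05 there were 412 genes, where 677 are expected by chance, and the smallest adjusted p was 0.713. It belonged to Rabl2, a small GTPase gene of cilia, at -0.79 ± 0.13. Ift27, another small GTPase gene of cilia, differed by -0.68 ± 0.14. Both were lower in 4 of 4 pairs, which the naming rule required of every gene that did not pass. Snhg11, Sez6l2, S100a9, Actl7a, Tmem198, Lyz1, Atxn7l2 and Ndufb1 completed the lower genes picked by the naming rule, with differences of -0.64 to -0.48. On the higher side Mymx, a gene of myoblast fusion, differed by 0.64 ± 0.13. Myod1, Ggn, Fitm1, Rbm45, Tmc8, Actc1, Disp3, Drd4 and Cyp2c38 completed that side, with differences of 0.46 to 0.66. None of these genes passed the test, and several lay near background, where an intensity of 0 is a log2 value of 5. Mean log2 values in mutants and controls were 5.14 and 5.63 for Actl7a, and 5.76 and 5.27 for Disp3. For the 7 genes with several probe sets, the dimmer ones differed less, from -0.49 for Ift27 to 0.06 for Myod1. That of Disp3 had the opposite sign, at -0.11. Without the LM pair 1 gene passed by limma, Nefl, at -1.20 with adjusted p = 0.033.

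The focal adhesion list, which holds partners of FAK, had a median of -0.03 over 30 members, and its camera adjusted p was 0.83. Extracellular matrix lay at -0.09, endothelium at -0.11, macrophage and leukocyte at -0.10 and neural crest at -0.04. Erythroid genes had a median of 0.14, hypoxia and glycolysis 0.07 and smooth muscle 0.04. None of these passed by camera, the nearest being hypoxia and glycolysis with adjusted p = 0.053 and endothelium with 0.055. The p53 targets and apoptosis, axon guidance, cartilage and bone, cell cycle, epithelium, glia, outflow tract, lower jaw, upper jaw and immediate early lists had medians between -0.08 and 0.00 and did not pass either. For the epithelium and axon guidance lists the median was negative while the mean and camera's direction were positive, and for outflow tract only the mean was negative. The number of called lists, 3 with all pairs, was 5 without the p75-sorted pair, 6 without the LM pair, 5 without the OFT pair and 5 without the UM pair.

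**Figure D1:**
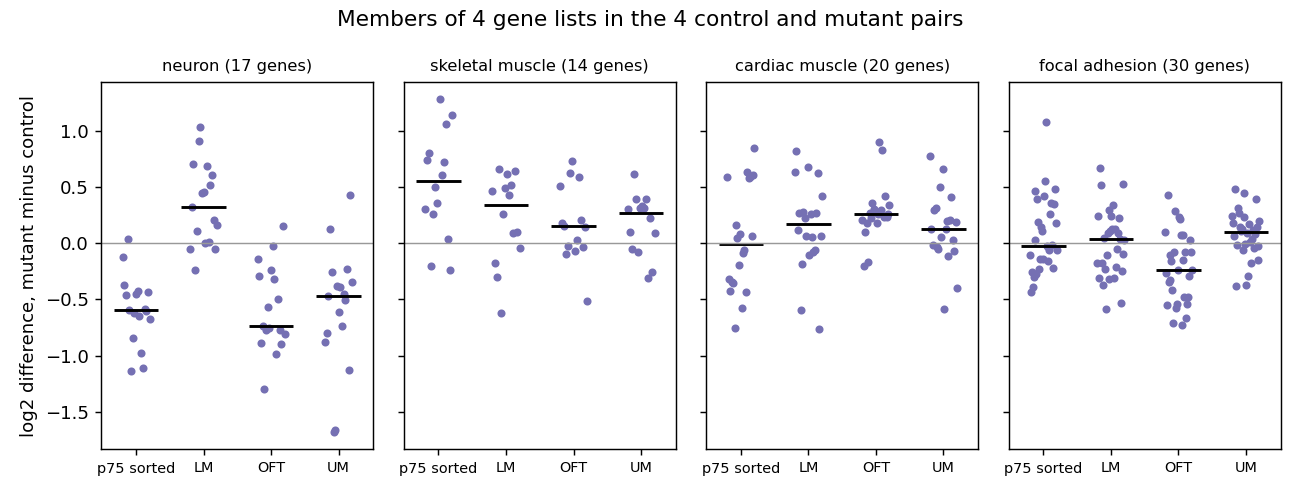
Log2 difference of mutant minus control in each of the 4 pairs for members of the neuron, skeletal muscle, cardiac muscle and focal adhesion lists, 1 point per gene with a black bar at the median. The neuron median is -0.59 in p75-sorted cells, -0.73 in OFT and -0.47 in UM, and 0.32 in LM.

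Within single origins the neuron list did not go the same way everywhere. Its median difference was -0.59 in p75-sorted cells, -0.73 in OFT and -0.47 in UM, each at percentile 0 of the matched random lists, and 0.32 in LM, at percentile 99.95. The skeletal muscle median was 0.55 in p75-sorted cells, 0.34 in LM, 0.15 in OFT and 0.26 in UM, at percentiles of 99.24 or higher. Cardiac muscle genes had a median of 0.26 in OFT, at percentile 100. The OFT pair also had negative medians for extracellular matrix (-0.27), focal adhesion (-0.24), endothelium (-0.29) and macrophage and leukocyte genes (-0.36), where the UM pair had medians of 0.14, 0.10, 0.13 and 0.02. In p75-sorted cells the immediate early and heat shock list had a median of -0.37, with 18 of 20 members lower in the mutant. The Gapdh ratio also differed within that pair, 2.82 in the control and 4.91 in the mutant, while the Actb ratio was 1.57 and 1.65. In OFT the same list had a median of 0.17, with 13 of 20 members higher, at percentile 99.92. These are differences between 2 arrays each, with no replicate check. The random lists were matched on signal and not on correlation within a list, estimated at 0.522 for neuron genes. An extreme percentile therefore does not show that a median is rare.

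By single genes, 53 differed at least 2-fold within p75-sorted cells, 76 within LM, 25 within OFT and 30 within UM. Neurofilament genes Nefl and Nefm differed by -1.68 and -1.66 in UM but by 0.90 and 1.03 in LM, and Ina, an intermediate filament gene of neurons, by -1.30 in OFT. Nes, the intermediate filament gene of neural progenitors, differed by 1.44 in p75-sorted cells, and Pik3cd, Nrip2 and Safb by 1.40. Hspa1b, a heat shock gene, lay at -1.36 there, with Zfp207 at -1.31 and H2az2 at -1.28. Kpnb1, an importin gene, differed by -1.86 in LM, -1.39 in OFT and 1.49 in UM. Rps27, a ribosomal protein gene, differed by -1.55 in LM and 1.18 in UM. Jpt1 went the other way, at 1.63 in LM and -1.29 in UM. Macroh2a3 was higher in the LM and OFT mutants, by 2.08 and 1.73. Kpnb1, Jpt1 and Macroh2a3 were read from probe sets of the x type, whose probes can match several transcripts. Such probe sets made up 4.25% of the genes tested, but 3 of the 53 genes differing 2-fold in p75-sorted cells, 15 of 76 in LM, 6 of 25 in OFT and 6 of 30 in UM. In LM, Lpar4 differed by 1.87, Ell2 by 1.54 and Pdk1, a kinase gene of the pyruvate dehydrogenase complex, by 1.46. Counts of 2-fold genes depended strongly on the pseudocount, with 784 to 1380 genes per origin at a pseudocount of 1.

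Sex-linked transcripts differed most between the arrays of the p75-sorted and OFT pairs. Xist, the transcript of the inactive X chromosome, had an intensity of 21.0 in the p75-sorted control and 2247 in the p75-sorted mutant. It lay between 4368 and 5032 on the LM, OFT and UM arrays. The Y-linked gene Eif2s3y had an intensity of 6.20 in the OFT control and 151 in the OFT mutant, and Uty 1.89 and 124. In the p75-sorted pair Eif2s3y had an intensity of 386 in the control and 140 in the mutant. By these transcripts the p75-sorted control appeared male and the OFT control female, while their mutants carried both Xist and Y-linked signal. Embryo sex and genotype thus cannot be told apart within these pairs, which also enter the genotype contrast.

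**Figure D2:**
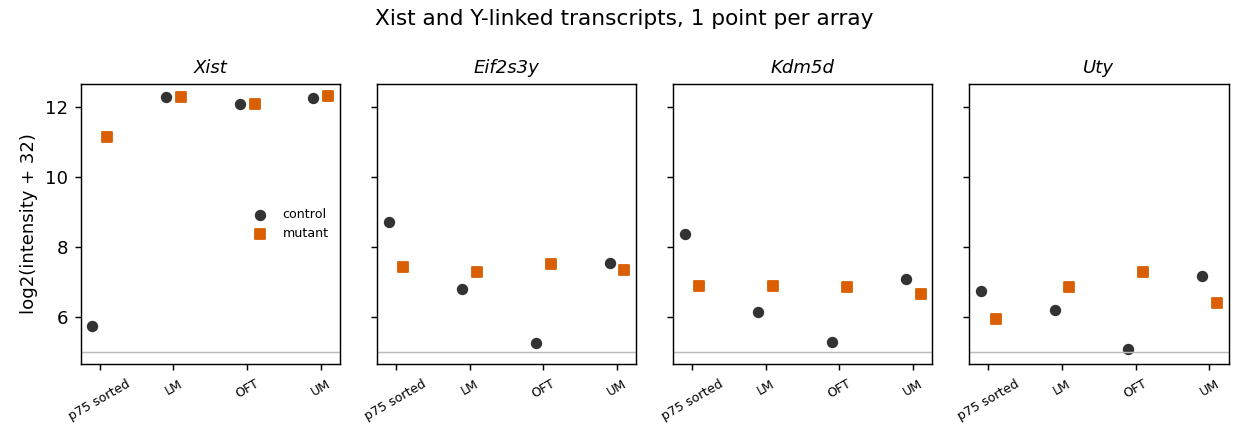
Log2(intensity + 32) of Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty on the 8 arrays, with circles for controls and squares for mutants, and a grey line at an intensity of 0. Xist is at 5.73 in the p75-sorted control and 11.15 or higher elsewhere, and the OFT control is the lowest array for each Y-linked gene.

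OFT against the mean of LM and UM asks how the OFT origin differs from the other unsorted origins. Heart muscle genes were far higher in OFT. Myl7, the atrial myosin light chain, rose by 6.94 ± 0.16 on the log2 scale (moderated SE, n = 2 arrays per origin), with adjusted p = 1.2e-10 by limma. Myh7, the beta myosin heavy chain, rose by 6.25 ± 0.19, and Tnnt2, cardiac troponin T, by 5.38 ± 0.16. Myl2, the ventricular light chain, had a mean log2 value of 11.47 in OFT and 5.47 in LM and UM. In LM and UM the mean log2 value was 5.07 for Myl7 and 5.43 for Myh7, where an intensity of 0 is 5, so the size of such differences depends on the pseudocount. Of 20 cardiac muscle genes 19 rose and 0 fell, and 19 passed adjusted over the list alone. This call held with an estimated correlation, at adjusted p = 0.046.

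Camera also called other lists higher, none of which held with an estimated correlation, and 5 of them follow here. In the outflow tract and second heart field list 13 of 19 genes rose and 3 fell, with Rgs5, a pericyte regulator of G protein signalling, at 5.14, Tbx20 at 5.09 and Gata6, both cardiac transcription factors, at 4.02, and adjusted p = 0.093 with an estimated correlation. Of 14 smooth muscle genes 13 rose, with Tagln at 4.49 and Acta2, the smooth muscle alpha actin, at 3.67, and adjusted p = 0.098 with an estimated correlation. Extracellular matrix had 17 of 27 genes higher and 1 lower, led by Eln, the elastin gene, at 2.76 and Tnc at 2.13, and adjusted p = 0.19 with an estimated correlation. Endothelium had 9 of 16 genes higher and 0 lower, with Tek at 1.49, and adjusted p = 0.18 with an estimated correlation. Focal adhesion had 10 of 30 genes higher and 0 lower, with Zyx at 1.22 and Vcl, the vinculin gene, at 1.10, and adjusted p = 0.20 with an estimated correlation. Adjusted over the list alone, 15 outflow tract, 13 smooth muscle, 19 extracellular matrix, 12 endothelium and 13 focal adhesion genes were higher. Ankrd1, Myl3, Myl4 and Tnni1 completed the genes with the largest increases, at 4.91 to 5.06.

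Most upper jaw patterning genes were lower in OFT. The list had 6 of 8 genes lower and 1 higher, with a median of -1.65 and adjusted p = 0.093 with an estimated correlation. Tbx22, a transcription factor of the palate, fell by 3.16, Alx1, a homeobox gene of facial mesenchyme, by 2.44, and Pou3f3 by 2.39. Pitx1, a homeobox gene of the lower jaw, fell by 3.45, and Msx1, a homeobox gene of facial mesenchyme, was 10.6-fold lower. Pax3, a neural crest transcription factor, fell by 3.19. Cxcl14, a chemokine gene, fell by 3.48, and Lhx8, AI606473, Crym and Apcdd1 had log2 differences between -3.03 and -2.66. Lower jaw patterning went both ways, with 4 of 11 genes higher, Hand2 at 2.27 and Edn1 at 1.68 among them, and 6 lower, and it did not pass by camera (adjusted p = 0.073). In the neural crest list 5 genes rose and 8 fell, Ednrb, an endothelin receptor gene, rising by 1.78, and its adjusted p was 0.28 with an estimated correlation. There were 6 upper jaw, 7 lower jaw and 8 neural crest genes lower when adjusted over the list alone. The neural crest list missed the threshold without the OFT mutant array, at adjusted p = 0.079, without either p75-sorted array, at 0.066, and without a filter on low values, at 0.094.

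Neuron genes were higher in OFT for 8 of 17 members and lower for 1. Nefm rose by 2.57 ± 0.37 and Nefl by 2.15 ± 0.37, and Prph rose by 1.32, and the list had adjusted p = 0.36 with an estimated correlation. Skeletal muscle had 6 of 14 genes higher and 1 lower. The members that moved most were Tcf21, a transcription factor also of cardiac mesenchyme, at 3.09 and Acta1 at 2.76, and the adjusted p was 0.18 with an estimated correlation. Erythroid genes were lower for 4 of 10, with Hbb-bh1, an embryonic globin, at -0.89, and adjusted p = 0.12 with an estimated correlation. Cell cycle genes fell for 2 of 22, Rrm2 by 0.75, with adjusted p = 0.11 by camera with an estimated correlation. Adjusted over the list alone, 10 neuron and 8 skeletal muscle genes were higher, and 7 erythroid and 1 cell cycle genes lower. Without the OFT control array Prph had adjusted p = 0.055, Rrm2 0.21 and Hbb-bh1 0.26, and Hbb-bh1 had 0.055 without the OFT mutant array. Nefl missed the threshold at a pseudocount of 1 and with the intensity trend.

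Cartilage and bone had 6 of 11 genes higher, Col9a1 by 1.44, with adjusted p = 0.18 with an estimated correlation. Hypoxia and glycolysis had 6 of 13 higher and 1 lower, Bnip3, a mitophagy gene induced by hypoxia, rising by 1.09, with adjusted p = 0.20 with an estimated correlation. Axon guidance had 8 of 24 genes higher and 1 lower, with the semaphorin gene Sema3c at 2.43, and adjusted p = 0.29 with an estimated correlation. Immediate early and heat shock genes were higher for 8 of 20, Ier3 by 1.39, with adjusted p = 0.36 with an estimated correlation. Macrophage and leukocyte genes were higher for 3 of 13, with adjusted p = 0.37 with an estimated correlation. Epithelium had 2 of 18 genes higher and 4 lower, Krt14, a keratin of basal epidermis, falling by 1.78, and adjusted p = 0.31 with an estimated correlation. Adjusted over the list alone, 7, 6, 8, 10, 5 and 3 genes were higher in the order given, and 7 epithelium genes lower. The glia and p53 lists did not pass by camera, with adjusted p = 0.063 and 0.79.

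Calls of these lists were lost without single arrays. Without the OFT control, macrophage and leukocyte had adjusted p = 0.12 and axon guidance 0.058. Without the OFT mutant, hypoxia and glycolysis and the immediate early list each had 0.088. Without the LM control, axon guidance had 0.057 and hypoxia and glycolysis 0.052. Axon guidance had 0.063 without the UM mutant. With the mean of a gene's probe sets, epithelium had 0.13 and axon guidance 0.14.

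In all, 2060 genes changed, 1533 higher and 527 lower; the count was 631 without the OFT control array and 1032 without the OFT mutant array, and 1012 at a pseudocount of 1. Of the 22 lists camera called 19, 14 higher and 5 lower, and fry 15. The share of higher genes moved with the probe sets used, since 1293 genes were higher and 789 lower with the mean of a gene's probe sets.

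LM against UM asks how these origins differ. Genes of lower jaw identity were higher in LM. Hand2, a transcription factor of the lower jaw, rose by 4.31 ± 0.22 (moderated SE, n = 2 arrays per origin), with adjusted p = 1.7e-06 by limma. Pitx1 rose by 2.71 ± 0.18, Cited1 by 2.04 ± 0.20 and Dlx5, a homeobox gene of the lower jaw, by 1.59 ± 0.20. All 11 members of the lower jaw list lay above 0 and 8 passed, or 11 adjusted over the list alone. Its call held with an estimated correlation, at adjusted p = 0.032. In the upper jaw list 4 of 8 genes fell and 1 rose, Alx1 falling by 3.13 ± 0.17, Tbx22 by 1.09 and Wnt5a by 1.06, with adjusted p = 0.063 with an estimated correlation, and 6 were lower adjusted over the list alone. Without the UM mutant array Tbx22 had adjusted p = 0.055 and Wnt5a 0.091, and Wnt5a had 0.052 without the UM control array.

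Some muscle genes were also higher in LM. In the skeletal muscle list 7 of 14 genes rose, Myog, a myogenic factor, by 2.61, Tnnt1 by 2.20 and Myf5 by 1.93, while Pax7, a factor of muscle and neural crest precursors, fell by 2.14; the list had adjusted p = 0.063 with an estimated correlation. Cardiac muscle had 5 of 20 genes higher, with adjusted p = 0.12 with an estimated correlation, Actc1 by 3.12 and Ttn by 1.64, though Ttn had adjusted p = 0.0501 without the UM mutant array. There were 11 skeletal muscle and 6 cardiac muscle genes higher when adjusted over the list alone. In the cardiac list Myl7 and Myh7 had mean log2 values of only 5.07 and 5.43 over LM and UM, where an intensity of 0 is 5. Smooth muscle had 1 of 14 genes higher, Acta2 at 2.67, with 7 members above 0 and 7 below, and it did not pass by camera (adjusted p = 0.82). Dlk1 rose by 2.55, while Gpr50, Dlx1as, Rtl3 and 3110099E03Rik were higher by 2.31 to 3.41.

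Of 17 neuron genes 5 fell in LM and 12 did not pass, and the list had adjusted p = 0.27 with an estimated correlation. Those that fell included Stmn2, a growth-cone protein gene, at -2.47 ± 0.27 and Neurod1, a neuronal transcription factor, at -1.97 ± 0.25, and 15 members lay below 0. Neural crest genes fell for 5 of 19, Tfap2b by 1.72 and Pax3 by 1.65, with adjusted p = 0.10 with an estimated correlation. Epithelium genes fell for 4 of 18, Epcam by 1.11, with adjusted p = 0.21 with an estimated correlation. Epcam had adjusted p = 0.25 without the UM mutant array, 0.11 without the LM mutant array and 0.051 without either p75-sorted array. Of 13 genes of the p53 targets and apoptosis list 1 fell, Pmaip1, with adjusted p = 0.24 with an estimated correlation. Its camera adjusted p was 0.033, and 0.27 without the UM control, 0.13 without the LM mutant and 0.061 without either p75-sorted array. In the order of these lists 9, 7, 7 and 1 genes were lower when adjusted over the list alone. Otx2, a head patterning factor, fell by 2.68, and Pmaip1, a p53 target that drives apoptosis, fell by 2.59. Sp8, Lhx2, Crym, Gata2 and Aldh1a3, an enzyme of retinoic acid synthesis, had differences between -2.53 and -2.06. The axon guidance, cartilage and bone, cell cycle and glia lists had medians between -0.17 and 0.14 here and did not pass by camera. The focal adhesion and extracellular matrix lists did not pass by camera either. Median, mean and camera's direction differed in sign for the outflow tract, smooth muscle and axon guidance lists. A total of 210 genes changed, 100 higher and 110 lower, and camera called 8 of the 22 lists, fry 6. That count was 130 without the LM control array, 111 without the UM control array and 117 without the UM mutant array, 64 at a pseudocount of 1 and 138 at a pseudocount of 100.

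Sorted cells against the mean of LM, OFT and UM asks how the p75-sorted cells differ from the other origins. No array is labelled as an unsorted sample of the same tissue. An effect of the sort therefore cannot be told apart from one of body region, pooling or RNA handling. All 8 genes of the glia list rose, 8 also adjusted over the list alone, with adjusted p = 0.19 with an estimated correlation. Sox10, a transcription factor of glia and neural crest, rose by 4.55 ± 0.16 (moderated SE, n = 2 sorted arrays), a 23.5-fold difference with adjusted p = 5.9e-09 by limma. Ngfr, which encodes the sorted p75 receptor, rose by 3.58 ± 0.17. Ednrb rose by 3.68, Fabp7, a fatty acid binding protein gene of glia, by 3.66 and Cdh19 by 2.98. Neuron genes rose for 14 of 17, Stmn3 by 3.11 and Tubb3, a neuronal tubulin gene, by 2.22, 14 also adjusted over the list alone, with adjusted p = 0.34 with an estimated correlation. In the neural crest list 7 of 19 genes rose and 6 fell, and it did not pass by camera (adjusted p = 0.27). That list shares Sox10, Erbb3, Foxd3 and Ednrb with the glia list, so these lists do not tell glia from neural crest.

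Of 20 immediate early and heat shock genes, many of them induced quickly by stress or growth signals, 19 rose, 19 also adjusted over the list alone, with adjusted p = 0.20 with an estimated correlation. Fos rose by 6.06 ± 0.16, Egr1 by 4.84, Fosb by 4.18 and Ccn1 by 3.37. These cells are the only sorted ones, and their arrays are those with the high Gapdh ratios of 2.82 and 4.91. Their Actb ratios of 1.57 and 1.65 lay within those of the other arrays. Zic1, a neural transcription factor, rose by 4.94, Vtn by 4.52, Gpr17 by 3.65 and Megf10 by 3.62. Extracellular matrix genes rose for 21 of 27 and fell for 3, Col6a1 rising by 2.19, with adjusted p = 0.34 with an estimated correlation. Focal adhesion genes rose for 17 of 30 and fell for 3, Git1 by 1.70 and Pxn, the paxillin gene, by 1.65, with adjusted p = 0.36 with an estimated correlation. In these 2 lists 21 and 19 genes were higher adjusted over the list alone. Focal adhesion had adjusted p = 0.11 with the mean of a gene's probe sets.

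Epithelium genes fell for 15 of 18 in the sorted cells, with adjusted p = 0.19 with an estimated correlation. Trp63, a factor of basal epithelium, fell by 1.82, while Cdh1, the E-cadherin gene, was 5.52-fold lower. Endothelium genes fell for 12 of 16, with Pecam1 at -2.31 and Emcn at -2.62, and adjusted p = 0.20 with an estimated correlation. Macrophage and leukocyte genes fell for 9 of 13 and rose for 1, Csf1r falling by 1.24, with adjusted p = 0.40 with an estimated correlation. Erythroid genes fell for 5 of 10, with Hba-x, an embryonic globin, at -1.77, and adjusted p = 0.23 with an estimated correlation. Lower jaw genes fell for 8 of 11, Pitx1 falling by 1.99, with adjusted p = 0.19 with an estimated correlation. Cardiac muscle genes fell for 13 of 20 and rose for 2, with Myl7 at -1.65, which missed the threshold at a pseudocount of 1, and Actc1 at 1.41; the list had adjusted p = 0.20 with an estimated correlation. Cell cycle genes fell for 11 of 22 and rose for 1, Kif11 falling by 1.07, with adjusted p = 0.20 with an estimated correlation. The skeletal and smooth muscle lists had more genes higher than lower and did not pass by camera. Skeletal muscle had 9 of 14 genes higher and 2 lower, Myod1 rising by 1.78, with a list median of 0.78 and adjusted p = 0.073, and smooth muscle 5 of 14 higher and 2 lower, with adjusted p = 0.62. Adjusted over the list alone, 15 epithelium, 14 endothelium, 9 macrophage, 5 erythroid, 8 lower jaw, 14 cardiac muscle and 11 cell cycle genes were lower. Net1, Ube2s, Uqcr10, Atp5l, Dsp and AY036118 were among the largest decreases, at -3.57 to -2.52. Dcun1d1, at -2.51, had a probe set of opposite sign, and Xist, at -3.78, rests on its near-background signal in the p75-sorted control. Myh9, a nonmuscle myosin gene at -0.92, turned to 0.19 with the mean of its probe sets and had adjusted p = 0.063 without the p75-sorted control.

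In all, 6380 genes changed, 3818 higher and 2562 lower; the count was 3238 without the p75-sorted mutant array, and the mean of a gene's probe sets gave 3119 higher and 3125 lower. The median difference of all genes was 0.07, and 0.12 at a pseudocount of 1 and 0.11 with the filter at the 60th percentile, so differences of this size are no more than that shift. Camera called 12 of the 22 lists, 5 higher and 7 lower, and fry 15. Among the lists not called, axon guidance and hypoxia and glycolysis had a negative median and a positive mean.

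**Figure D3:**
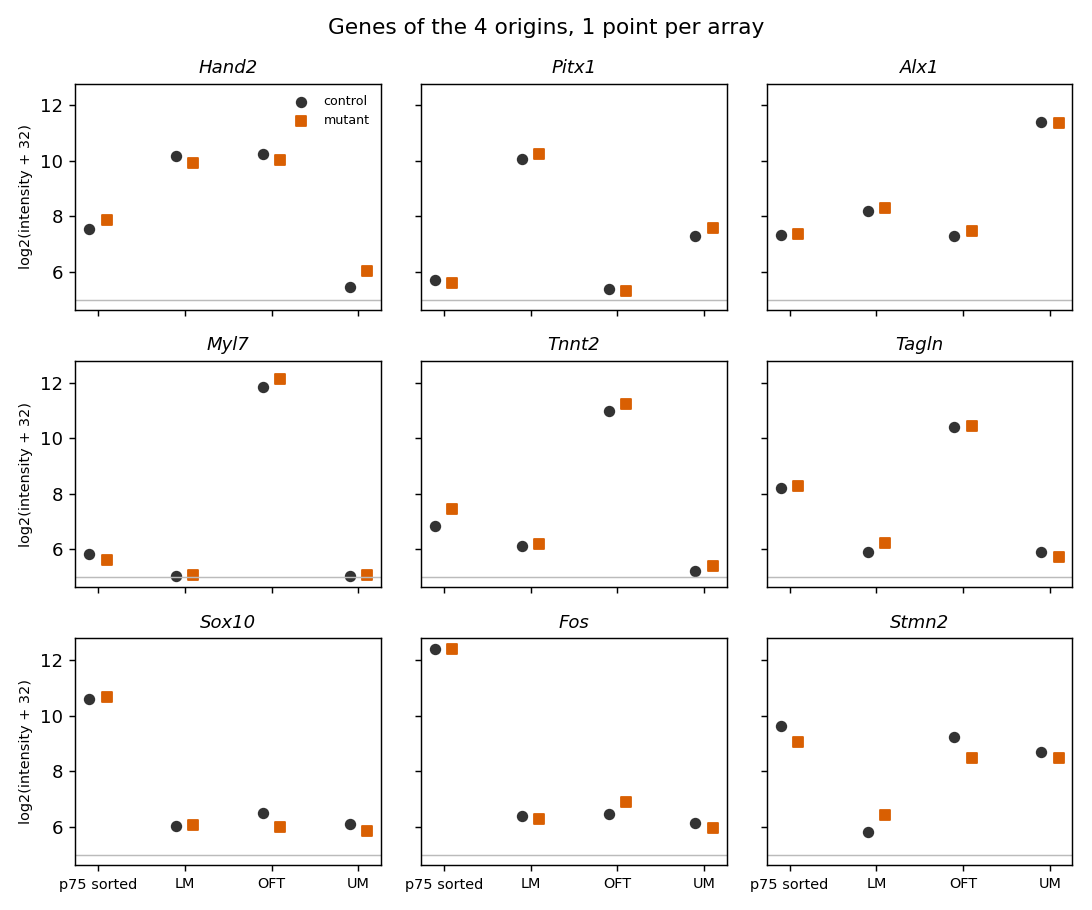
Log2(intensity + 32) of 9 genes in the 4 origins, with circles for controls, squares for mutants and a grey line at an intensity of 0. Myl7 differs between OFT and the mean of LM and UM by 6.94, Hand2 between LM and UM by 4.31, and Fos between sorted cells and the other origins by 6.06.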

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

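A value was picked out here when 1 of 4 arrays, or 1 of 4 control and mutant pairs, lay far from the other 3 relative to the range of all 4. Of 64 such groups of 4 values 10 were picked out, and several of the 10 come from the same arrays. The cutoff picks about 1 in 20 groups when all 4 values come from 1 normal distribution. The groups here mix 4 origins and include genes chosen by the naming rule. That rate therefore cannot tell whether 10 is more than chance gives.

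The Gapdh ratio of 3' to 5' signal was 2.818 in the p75-sorted control, against 0.708 to 0.986 in the other controls, and 4.908 in the p75-sorted mutant, against 0.700 to 0.750 in the other mutants. The 18S signal was 6083 in the p75-sorted control, against 350 to 1228, and 8542 in the p75-sorted mutant, against 314 to 793. Both sets of values single out the sorted pair, the only one labelled as sorted. The Actb ratio was screened in the same way and was not picked out.

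Xist had a log2 value of 5.729 in the p75-sorted control, against 12.10 to 12.28 in the other controls, and its mutant-minus-control difference was 5.425 in that pair, against -0.00 to 0.04 in the others. Kdm5d, a Y-linked gene, had a log2 value of 6.664 in the UM mutant, against 6.866 to 6.879 in the other mutants, a small gap picked out because those 3 values lie close together.

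Among genes that did not pass between mutant and control, the p75-sorted pair stood apart for Rbm45, at 1.223 against 0.3996 to 0.5058. The OFT pair stood apart for Cyp2c38, at 0.3119 against 0.493 to 0.520, and for Lyz1, at -0.9872 against -0.443 to -0.334.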

How the results depend on the processing

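The fit on the 6 LM, OFT and UM arrays was chosen after seeing the data; it gave 1887 genes for OFT and 161 for LM against UM. Of 130 alternative counts 98 stayed within 1.5 times the reported count. Of the genes named as changed, 56 of 86 for OFT, 16 of 43 for LM against UM and 77 of 98 for p75-sorted cells passed under every alternative run for that contrast. Where a count or value changed, the cause was not tested. Over fits without 1 array or pair, the genotype contrast had 0 to 1 genes and 5 to 6 lists, OFT 631 to 2154 genes, LM against UM 111 to 227 and p75-sorted cells 3238 to 6428. Such fits assume that a lone array of an origin varies like the others. A pseudocount of 1 gave 1012 genes for OFT and 64 for LM against UM, a pseudocount of 100 gave 138 for the latter. Without filter LM against UM had 140 genes. Genotype lists numbered 5 with the mean of a gene's probe sets. With an estimated correlation 0, 1, 1 and 0 lists were called in the genotype, OFT, LM against UM and p75 contrasts, where the preset correlation called 3, 19, 8 and 12; fry called 0 genotype lists. With no replicate block, that is without the origin term, the genotype contrast had 0 genes, 46 at an unadjusted p under 0.05, and 2 lists; cardiac muscle lost its call. Genes differing 2-fold within p75-sorted, LM, OFT and UM pairs numbered 53, 76, 25 and 30. They were 856, 1380, 784 and 1040 at a pseudocount of 1, then 20, 13, 7 and 8 at a pseudocount of 100, and 16, 28, 13 and 13 with the mean of probe sets. Signal over background limits dim genes, whose differences grow as the pseudocount falls. The median of all genes in the p75 contrast was 0.07, and 0.12 at a pseudocount of 1.

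Directions that turned belonged to genes that had not passed, except Myh9 in the p75 contrast. Myh9 went to 0.1891 with the mean of probe sets. Under that setting Sox10 went to 0.05993, Nfatc1 to 0.007208, Mdm2 to 0.04201 and Sesn2 to 0.1042 in the genotype contrast, and the neural crest median within UM to 0.03663. Quantile normalization took Actg1 to -0.001497 and Actb to -0.03947 in LM against UM. Over fits without 1 pair, genotype differences ranged from -0.2327 to 0.0005245 for Ccnb2, -0.6606 to 0.03011 for Hspa1b, -0.1186 to 0.3602 for Cdkn1a, -0.1811 to 0.03338 for Pou3f3, -0.1055 to 0.3359 for Cdh1, -0.0009866 to 0.1915 for S100b, -0.05889 to 0.6364 for Pdk1, -0.2312 to 0.07933 for Sesn2, -0.1512 to 0.02192 for Shox2, -0.2331 to 0.09507 for Dlx6 and -0.05141 to 0.2219 for Hand2. Over fits without 1 array, LM against UM ranged from -0.01904 to 0.4593 for Top2a, -0.09623 to 0.7252 for Hbb-y, -0.8397 to 0.1009 for Gfra3, -1.162 to 0.3527 for Pdk1, -0.7711 to 0.2509 for Hspa1a, -1.047 to 0.1598 for Fcer1g, -0.2076 to 0.7463 for Actg1, -0.4017 to 0.8584 for Actb, -0.2415 to 0.6418 for Acan and -0.04142 to 0.8134 for Cav1.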

Other observations

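Tests chosen only after the result was seen are those of the correlation within lists, of ganglion tissue and of exchanged UM labels; the others were set before their result was seen.

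Focal adhesion and matrix genes had medians of opposite sign in the OFT and UM pairs. In OFT 22 of 30 focal adhesion genes and 22 of 27 extracellular matrix genes were lower in the mutant, and all 13 macrophage and leukocyte genes were lower there. In UM 20 of 30 focal adhesion genes were higher in the mutant, at percentile 91.07, and 19 of 27 extracellular matrix genes, at percentile 95.78. In LM the focal adhesion median lay at percentile 90.71, but the extracellular matrix median was -0.15, with 18 of 27 genes lower. In p75-sorted cells the focal adhesion median was -0.02 and the extracellular matrix median 0.10. In UM the lower jaw list had a median of 0.25 in the mutant, at percentile 98.64, with 8 of 11 members higher. In LM the cell cycle list had a median of -0.26, at percentile 1.55. Each is a difference between 2 arrays, and the difference between origins was not tested.

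For the mutant against control contrast, other splits of the 8 arrays were counted. Of 35 splits, 8 part all 4 pairs, 24 part 2 pairs and 3 part none. Among the 8 the share cannot fall under 0.125, so they are too few to reach 0.05. The real split called 0 genes and the highest other split of the 8 also called 0, so all 8 gave as many; for lists the real split called 3, the highest other 5, and 6 of the 8 gave at least as many. The splits that part 2 pairs differ in leaving 2 origins unparted, and they called up to 1 gene and 10 lists. At an unadjusted p under 0.05, exchanging the labels of LM and OFT together gave 2042 genes and exchanging those of UM gave 1233, against 412 with the labels as given, which points to a structure of the samples in which the differences of LM and OFT run against those of UM and p75-sorted cells.

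A first pattern is that neuron genes lay lower and skeletal muscle genes higher in the mutants. Genes within a list may be more correlated than the preset of 0.01, with estimates of 0.522 for neuron and 0.058 for skeletal muscle genes. With an estimated correlation the smaller camera adjusted p of the pair was 0.284, so neither call held. This loss cannot show that the preset was too small. In the OFT contrast the cell cycle list, with an estimate of 0.008, also went from a camera adjusted p of 1.2e-04 to 0.11. A lower share of ganglion tissue as a whole is another candidate explanation, and it would lower glia genes with the neuron genes. The glia median was -0.33 in OFT and -0.15 in UM, but 0.09 in p75-sorted cells and 0.11 in LM. The mean mutant-minus-control difference of the glia list lay above that of the neuron list by 4.43 SE in p75-sorted cells, 2 SE in UM and 1.56 SE in OFT, and below it by 1.49 SE in LM, where neuron genes were higher in the mutant, but this SE is over genes of 1 pair of arrays, so ganglion tissue and a change in neurons alone cannot be told apart. An effect of the FAK mutation stays open.

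A second pattern is that the mutant-minus-control differences of LM and UM ran opposite across genes, with a correlation of -0.33, while LM and OFT correlated at 0.28; genes are not independent replicates. Intensity-dependent scaling would have brought the LM and UM correlation near 0 after quantile normalization, and it stayed at -0.319. That check covered all genes together and was not repeated among bright genes alone. Other technical differences between arrays were not tested. The spike-in controls, for example, had a geometric mean intensity of 2531 on the LM control and 1206 on the LM mutant. Genes close to background were not the source of the pattern, since the LM and UM correlation was -0.745 in the brightest of 4 equal groups of genes and -0.08 in the dimmest. Exchanged labels in the UM pair could produce it: with them exchanged the UM difference correlated at 0.33 with LM and 0.20 with OFT but at -0.13 with p75-sorted cells, the last from -0.166 to -0.115 in 4 of 5 settings and -0.0605 at a pseudocount of 1, and the UM neuron median of -0.47 and skeletal muscle median of 0.26 share their sign with p75-sorted cells and OFT only as labelled, so this stays open. Exchanged labels in the LM pair, where the neuron median was 0.32, stay open too, though they would turn the LM and OFT correlation of 0.28 negative and leave the LM skeletal muscle median of 0.34 opposite to the other origins; exchanging UM called 0 genes and 1 list and exchanging LM 0 genes and 5 lists, with 1233 and 606 genes at an unadjusted p under 0.05 by limma, which excludes neither, and a biological difference between the origins was not tested.

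Another pattern is the level of Ttr, which encodes transthyretin, a carrier protein made by yolk sac, liver and choroid plexus. Its intensity was 814 in the OFT control and 6.82 in the OFT mutant, and it was also high in p75-sorted cells, with log2 values of 9.995 and 8.953. A fault of 1 probe set was argued against, since all 4 probe sets of Ttr were higher in the OFT control, the smallest difference being 2.48. Yolk sac or liver tissue was argued against by a list of 14 measured genes, whose median control-minus-mutant difference was -0.0268, with Afp at a log2 value of 5.22 and Alb at 5.48 in the OFT control. For choroid plexus the median over 9 measured genes was 0.153 and none of the 5 brightest differed by 1, which argues against a share large enough to lift them; most of these genes lay near background, so a smaller share may remain.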
